A study of Homo sapiens with 22 samples.

How the data were processed

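The series holds RNA-seq of tumour tissue from 22 patients with non-small cell lung cancer, 1 library per patient. Libraries were made with a stranded mRNA kit that selects polyadenylated RNA and sequenced on an Illumina instrument, per the labels' protocols. The patients were assigned to groups A (6), B (10) and C (6) as the labels give them; the labels explain neither the letters nor the histology.

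One table of gene values was used. The FPKM values are as deposited by the authors: TopHat2 2.0.14 and hg19 are named in the submitters' processing notes, with no role or order, while the counter and the annotation are not given in the sources used here. The unit was inferred, since the labels do not name it: values are never negative and not whole, and the sum of value times the longest transcript length in kilobases, over the 18438 symbols with a known length, came to between 884322 and 1055273 per library. Relative depth was found from low values (under 0.05 FPKM). In each of 231 pairs of libraries the ratios of such values lay on steps of small whole numbers, 82.8% of them against 2.55% after random shifts, and 1 set of depths met all pairs. Depth relative to the geometric mean ran from 0.732 to 1.40. The absolute depth, and the counting error of a value, are unknown because gene lengths of the annotation are not given in the sources used here, and no count test was run. Between 2223 and 2912 genes per library were listed at 0. Values of 8 libraries are rounded to 5 significant digits and those of 14 are not, which was found in the table and treated as a technical batch.

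The table has 19752 lines with a gene. The 121 lines of genes on the Y chromosome, XIST and TSIX were left out of every step. The 700 lines of 242 repeated symbols were averaged per symbol, which left 19173 symbols. Genes with at least 1 FPKM in at least 6 libraries, 13442 in all, were tested. Values were taken as log2(FPKM + 1), a scale on which folds of genes with low values are understated. No scaling between libraries was added to the authors' own.

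Group means were compared with limma 3.58.1 in R 4.3.3, with trend and robust empirical Bayes, in 1 fit over all 22 libraries with 3 contrasts (B minus A, C minus A and C minus B) and a moderated F test over the groups. P-values were adjusted by Benjamini and Hochberg's method over the genes tested, with a threshold of 0.05. Error values of log2 differences are limma's standard errors.

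Of 32 gene lists fixed before the data were examined, as were the groups, the tests, the first set of other settings and the rule for named genes, 29 had at least 5 measured genes. Not tested were neuroendocrine genes (4 measured), red blood cell genes (3) and mitochondrially encoded genes (0). Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 29 lists of a comparison. An estimated correlation, fry, and an exact permutation test of the score of each library were alternatives. The score is the mean over a list's genes of the z score of log2(FPKM + 1). The smallest p that the permutation test can give is 0.000125 for the comparisons with B and 0.00216 for C against A. A permutation test stratified by number format was added after seeing the data. Sublists of alveolar type 2, alveolar type 1, club and pan-leukocyte genes served the tests in the closing section.

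The WNT target score was related to the cytotoxic, interferon gamma and dendritic cell scores by Pearson's r and Spearman's rho, each tested by 1e+05 permutations and adjusted over the 3 relations.

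Genes named in the text were chosen by a rule. For each comparison these were the 8 genes with the smallest p among those higher and the 8 among those lower, with an adjusted p under 0.05 and a log2 difference of at least 1. From each list called by camera, up to 4 members with the smallest p in the list's direction were added. From the WNT target, WNT ligand and receptor, and cytotoxic lists, called or not, the 3 members with the smallest p were added. AXIN2, LEF1, TCF7, CTNNB1, CD8A, GZMB, IFNG, CD274, FOXP3 and MKI67 were taken in every comparison. Segment genes of immunoglobulins and T cell receptors and features with no approved symbol were left out of the first step. The rule gave 88, 103 and 115 genes for B against A, C against A and C against B, of which the text names a part, and some are not reported here.

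Other settings fixed at the start were pseudocounts of 0.1 and 5, no filter, a filter of 5 FPKM, quantile normalisation, limma without trend and robust, array weights, only the 2 groups compared, the squamous and alveolar scores as covariates, and leaving out each library in turn. Added after seeing the data were the number format as a covariate, the log2 relative depth as a covariate, only the 14 libraries not rounded, only the 8 rounded, and leaving out the 1 library of B and the 2 of A nearest the other group on the first principal component. The libraries were also regrouped at random 100 times, the real grouping included, and again within each number format. Sequences and coordinates were not used.

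The procedure was tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale among 13442. For B against A it recovered 61% and 93% with 5 false calls of 159, for C against A 59% and 93% with 6 of 158, and for C against B 54% and 90% with 8 of 152. The changed list was called in each and 0 null lists were. The simulated noise was independent between genes, whereas the estimated correlation within the real lists reached 0.819. The simulation therefore does not show how often camera calls a real list falsely. Tables were read and figures drawn with python 3.11.15.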

Results

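RNA from the tumour tissue of 22 patients with non-small cell lung cancer was sequenced, with 1 library per patient. Non-small cell lung cancer is the commonest class of lung cancer and consists mostly of adenocarcinomas, which arise from glandular and alveolar cells, and squamous cell carcinomas, which arise from the lining of the airways. The labels place the patients in 3 groups named A (n = 6), B (n = 10) and C (n = 6). They do not say what the letters stand for, how the patients were assigned, or what histology a tumour had. The title of the series names the WNT pathway and the escape of immunogenic cancer cells from the immune system, so the comparisons below ask how WNT genes, immune cell genes and tumour cell genes differ between the groups. If the groups were formed from these same measurements, the p-values below would not be independent evidence of a difference.

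The values are read as FPKM, a unit scaled for gene length and library size. The labels do not name the unit, which was inferred from the values. Steps between low values gave the depth of the libraries relative to one another, 1.13 ± 0.162 in A (SD, n = 6), 1.02 ± 0.191 in B (SD, n = 10) and 0.888 ± 0.0418 in C (SD, n = 6). Depth differed between C and A (mean log2 difference -0.337, exact permutation p = 0.00433), while the absolute depth is unknown. The FPKM of a library summed to between 270034 and 369387 over all genes, and between 11815 and 12955 genes stood at 1 FPKM or more. Differences are given on the log2(FPKM + 1) scale, which understates the change of genes with low values, with adjusted p from limma over 13442 genes. The table holds 2 number formats: 8 libraries (2 of A, 2 of B and 4 of C) are rounded to 5 significant digits and 14 (4 of A, 8 of B and 2 of C) are not. This split was treated as a technical batch, and for lists called by camera, values within the libraries that are not rounded and within those that are rounded stand beside the pooled ones. A permutation test stratified by number format was added after seeing the data and is given where it moved a list across the threshold. Because the 3 comparisons share libraries, they are not independent of one another.

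Across all 3 groups, 4877 of the 13442 genes differed between at least 1 pair of groups in limma's moderated F test. The first principal component held 30.9% of the variance. Its mean score was -61.0 ± 25.7 in A (SD, n = 6), 29.5 ± 26.5 in B (SD, n = 10) and 11.8 ± 22.9 in C (SD, n = 6). All of C lay above A, but the lowest library of B (-38.3) lay within the range of A (-89.0 to -27.5). The second component held 13.4% and set C (35.4 ± 21.8) apart from B (-19.6 ± 11.8). Within C it also went with the number format. The 4 rounded libraries scored 25.9 to 59.8 and the 2 not rounded 5.55 and 18.6. Correlations between pairs of libraries over these genes ran from 0.674 to 0.949, with no pair close enough to be the same library.

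**Figure D1:**
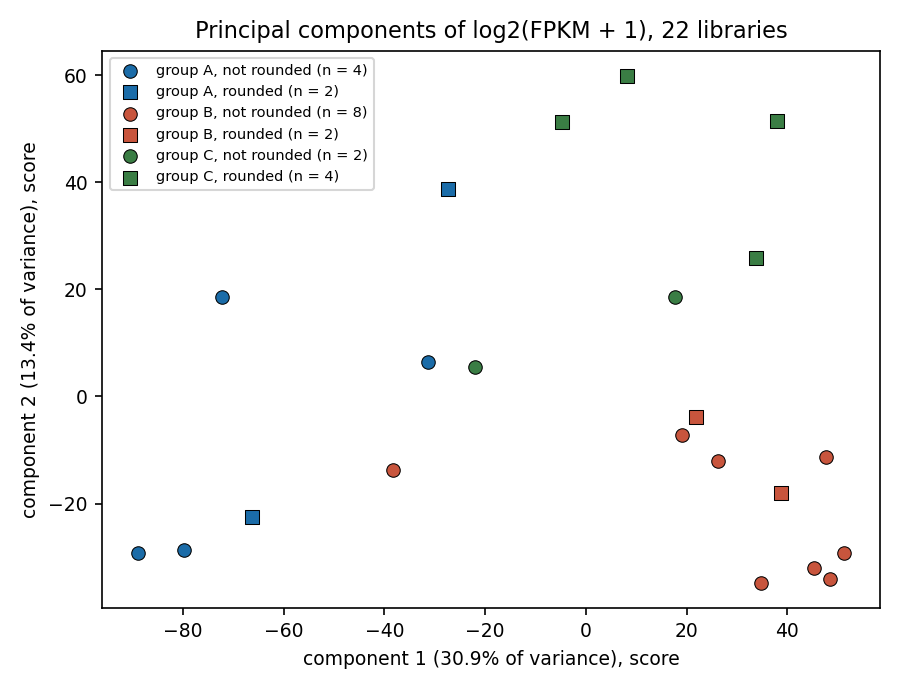
First and second principal components of log2(FPKM + 1) over 13442 genes, 1 point per library, with colour for the group and circles or squares for libraries not rounded or rounded. Group A lay at the low end of the first component (-89.0 to -27.5), B between -38.3 and 51.3 and C between -22.1 and 37.9.

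Tumours of group B had higher levels of alveolar and club cell, endothelial, MHC class II and dendritic cell genes than tumours of group A, and lower levels of cell cycle, antioxidant and squamous genes. These calls rest on camera with its preset correlation and on the permutation test. With an estimated correlation camera called 0 lists (3 at an unadjusted p under 0.05). In all, 4616 of 13442 genes differed, 2650 higher and 1966 lower in B, and 1251 and 826 of these differed by at least 1 on the log2 scale. With quantile normalisation 2189 were higher and 2412 lower, so which direction held the majority depends on the scaling. MUC1, a membrane mucin of glandular epithelium, stood at 330.0 ± 173 FPKM in B (SD, n = 10) against 14.4 ± 5.47 in A (SD, n = 6), a log2 difference of 4.25 (SE 0.50, limma adjusted p = 2.22e-05). UCHL1, a ubiquitin hydrolase of neurons and neuroendocrine cells, stood at 4.54 ± 3.46 FPKM in B against 150.4 ± 63.1 in A (log2 difference -4.87, SE 0.54, limma adjusted p = 1.76e-05). Each of the genes named from the smallest p-values lay beyond the median of A in 10 of 10 libraries of B. Higher in B were also TMEM173, which encodes the DNA sensing adaptor STING (1.73), the necroptosis kinase RIPK3 (1.56), the carboxypeptidase CPM (2.56), the serine protease TMPRSS2 (2.60), the myeloid nuclear protein MNDA (2.18) and the endothelial adhesion molecule ICAM2 (1.93). Lower in B were the ribosome assembly GTPase LSG1 (-1.69), the spindle protein FAM83D (-3.07), the lipoprotein receptor LRP8 (-2.004) and the homeobox gene DLX6 (-2.33).

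The largest list differences between B and A concerned the identity of the epithelium. Of the 21 alveolar and club cell genes measured, 19 were higher, 0 lower and 2 did not pass (20 higher and 0 lower adjusted over the list alone), with a median log2 difference 3.23, 3.21 not rounded and 3.50 rounded. Its call held in the permutation test (exact permutation adjusted p = 0.00121) but not with a correlation estimated from the data (adjusted p = 0.338 with an estimated correlation). SLC34A2, a phosphate transporter of alveolar type 2 cells, reached 328 ± 280.4 FPKM in B against 14.5 ± 13.5 in A, and AGER, a marker of alveolar type 1 cells, 37.98 ± 26.9 against 4.82 ± 3.35. Of the 23 squamous differentiation genes, 0 were higher, 15 lower and 8 did not pass (0 higher and 19 lower adjusted over the list alone), with a median log2 difference -3.53, -3.72 not rounded and -3.48 rounded (exact permutation adjusted p = 0.0311; adjusted p = 0.496 with an estimated correlation). SOX2, a transcription factor of airway basal cells, stood at 3.62 ± 5.91 FPKM in B and 85.7 ± 47.3 in A, and TP63, the basal cell regulator, at 8.70 ± 24.4 and 87.04 ± 74.01. One library of B scored 1.78 on the squamous list, above the highest of A (1.47) and the other 9 of B (at most -0.314). That library also lay within the range of A on the first principal component (-38.3). Ciliated cell genes were not called by camera, with 3 of 9 higher (median log2 difference 0.63). Endothelial genes, from blood vessels, were higher in 17 of 18 cases (18 adjusted over the list alone), with a median log2 difference 1.71, 1.72 not rounded and 1.47 rounded (exact permutation adjusted p = 0.00121; adjusted p = 0.338 with an estimated correlation). PECAM1 stood at 57.9 ± 27.6 FPKM against 16.3 ± 6.98, and CLEC14A at 36.3 ± 25.4 against 5.69 ± 3.31.

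Cell cycle and antioxidant genes went the other way. All 26 of 26 proliferation genes were lower in B (26 adjusted over the list alone), with a median log2 difference -1.999, -2.23 not rounded and -1.27 rounded (exact permutation adjusted p = 0.00517; adjusted p = 0.338 with an estimated correlation). MKI67, the usual marker of dividing cells, stood at 4.10 ± 4.59 FPKM in B and 13.8 ± 3.96 in A (log2 difference -1.89), and the replication helicase gene MCM4 at 9.15 ± 7.04 and 55.9 ± 31.6. Of the 20 xenobiotic and NRF2 genes, which detoxify oxidants, 0 were higher, 18 lower and 2 did not pass (0 higher and 19 lower adjusted over the list alone), with a median log2 difference -2.96, -2.46 not rounded and -3.69 rounded (exact permutation adjusted p = 0.00145; adjusted p = 0.338 with an estimated correlation). Glutathione synthesis gene GCLC stood at 9.90 ± 2.80 FPKM against 84.8 ± 48.6, and SRXN1, which restores oxidised peroxiredoxins, at 14.03 ± 3.83 against 173 ± 121. Among 21 hypoxia and glycolysis genes, 0 were higher, 8 lower and 13 did not pass (0 higher and 8 lower adjusted over the list alone), with a median log2 difference -0.70, -0.83 not rounded and -0.39 rounded (exact permutation adjusted p = 0.0482; adjusted p = 0.496 with an estimated correlation). SLC2A1, the glucose transporter GLUT1, had a log2 difference of -3.14. Among 24 DNA repair and mutator genes, 2 were higher, 9 lower and 13 did not pass (2 higher and 11 lower adjusted over the list alone), with a median log2 difference -0.12, -0.25 not rounded and -0.16 rounded (exact permutation adjusted p = 0.0373; adjusted p = 0.53 with an estimated correlation). The lower members included MSH6, a mismatch repair gene (-1.30), and BRCA1, a gene of homologous recombination (-1.38).

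Camera called 7 immune lists higher in B than in A, none of them with an estimated correlation. The dendritic cell list shares LAMP3 with the alveolar and club cell list. Which cells carried the genes of these lists was not tested. Of 16 MHC class II genes, 13 were higher, 0 lower and 3 did not pass (13 higher and 0 lower adjusted over the list alone), with a median log2 difference 1.87, 2.14 not rounded and 1.68 rounded (exact permutation adjusted p = 0.00145; adjusted p = 0.338 with an estimated correlation). HLA-DRA stood at 1935 ± 657 FPKM against 492 ± 292. Of 13 dendritic cell genes, 9 were higher, 0 lower and 4 did not pass (11 higher and 0 lower adjusted over the list alone), with a median log2 difference 1.54, 1.65 not rounded and 1.28 rounded (exact permutation adjusted p = 0.00121; adjusted p = 0.338 with an estimated correlation). They included the IgE receptor gene FCER1A (2.79) and the lectin gene CLEC10A (1.61). Macrophage and monocyte genes were higher in 10 of 20 cases (11 adjusted over the list alone, median log2 difference 1.26, 1.55 not rounded and 1.21 rounded, exact permutation adjusted p = 0.00845; adjusted p = 0.496 with an estimated correlation). Among the macrophage genes were the mannose receptor MRC1 (2.07) and CSF1R (1.44). Neutrophil and mast cell genes were higher in 8 of 14 (9 adjusted over the list alone, median log2 difference 1.08, 1.13 not rounded and 0.82 rounded, exact permutation adjusted p = 0.00241; adjusted p = 0.496 with an estimated correlation). KIT, the receptor on which mast cells depend, had a log2 difference of 1.76. Type I interferon response genes were higher in 12 of 22 (14 adjusted over the list alone, median log2 difference 1.06, 0.83 not rounded and 1.73 rounded, exact permutation adjusted p = 0.0393; adjusted p = 0.496 with an estimated correlation). IFIT1, an antiviral RNA sensor, was one of these (1.70). MHC class I genes were higher in 6 of 18 (5 adjusted over the list alone, median log2 difference 0.61, 0.82 not rounded and 0.37 rounded, exact permutation adjusted p = 0.0437; adjusted p = 0.53 with an estimated correlation). B2M, their shared light chain, stood at 5051 ± 1300.0 FPKM against 2515 ± 924. Reads of HLA genes can be shared between close relatives, so their levels are uncertain.

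Cytotoxic T and NK genes differed less evenly between B and A. Of 25 genes, 9 were higher, 1 lower and 15 did not pass (11 higher and 1 lower adjusted over the list alone), with a median log2 difference 0.62, 0.86 not rounded and 0.19 rounded (camera adjusted p = 0.00714; exact permutation adjusted p = 0.0443; adjusted p = 0.561 with an estimated correlation). The T cell receptor components CD3D and CD3E were higher (1.04 and 1.08), whereas CD8A did not pass (0.46, limma adjusted p = 0.248; 0.24 without A replicate 1), nor did the granule protease GZMB (-0.37, adjusted p = 0.459) or IFNG (-0.24, adjusted p = 0.582). Among the 8 rounded libraries the direction of the list's test turned. CD274, which encodes the checkpoint ligand PD-L1, stood at 5.50 ± 2.45 FPKM in B and 17.7 ± 15.2 in A (adjusted p = 0.116), and FOXP3, the regulator of suppressive T cells, at 2.06 ± 1.06 and 1.16 ± 0.784 (adjusted p = 0.131). Not called by camera were checkpoint genes (median log2 difference 0.13), regulatory T cell genes (0.50), interferon gamma response genes (0.38), B cell and plasma cell genes (0.33), chemokines (0.71) and fibroblast and matrix genes (0.24). The permutation test called 5 lists that camera did not, among them regulatory T cell genes (exact adjusted p = 0.00724), chemokines (exact adjusted p = 0.00869) and ciliated cell genes (exact adjusted p = 0.0482).

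WNT genes differed in both directions between B and A. Of 24 beta-catenin target genes, 0 were higher, 5 lower and 19 did not pass (0 higher and 2 lower adjusted over the list alone), with a median log2 difference -0.61, -0.35 not rounded and -0.98 rounded. The list was called lower by camera (camera adjusted p = 0.0339), but not by the permutation test (exact permutation adjusted p = 0.155) or fry (fry adjusted p = 0.0864). It was not called either when the correlation was estimated (adjusted p = 0.519 with an estimated correlation). Camera's call was also lost with a pseudocount of 0.1 (median -0.69, adjusted p = 0.0524), with the stricter filter (-0.54, 0.138) and among the 14 libraries not rounded (-0.35, 0.168). It held with quantile normalisation (camera adjusted p = 0.0435) and among the 8 rounded libraries (1.31e-04). It also held with the squamous and alveolar scores (0.00630), the number format (0.0404) or relative depth (0.0131) as covariates. The 5 lower members were KREMEN1, a receptor of the inhibitor DKK (5.71 ± 5.63 FPKM in B, 37.5 ± 20.8 in A, log2 difference -2.61), the receptor gene FZD7 (-2.09), MYC (-1.02), the ligase gene ZNRF3 (-0.85), which removes WNT receptors, and BAMBI, a pseudoreceptor of TGF-beta that was named here after its values were seen. AXIN2, the most widely used readout of the pathway, did not differ detectably (4.77 ± 2.83 FPKM in B, 15.9 ± 30.1 in A, log2 difference -0.24, limma adjusted p = 0.78), nor did LEF1 (adjusted p = 0.158), TCF7 (0.201) or CTNNB1, the gene of beta-catenin (0.246). The difference of AXIN2 was -0.40, -0.49, -0.46, -0.56, -0.03 and 0.50 without A replicates 1 to 6 in turn, -0.12 without B replicate 2 and -0.14 without B replicate 6. The high scores of the list came from 2 of the 6 libraries of A (0.990 and 1.62), while the other 20 libraries scored at most 0.109. The median of the list went from -0.61 to -0.30 without A replicate 6. It went to 0.15 without 2 libraries of A and 1 of B that lay nearest the other group on the first component. Those 2 libraries of A are the 2 with the high scores. Among 26 WNT ligands and receptors, 5 were higher, 5 lower and 16 did not pass (5 higher and 5 lower adjusted over the list alone). WNT5A (-2.76) and FZD6 (-1.55) were lower and FZD4 (1.39) higher. Machinery genes (2 higher and 8 lower of 28, median -0.13) missed camera's threshold (camera adjusted p = 0.058) and passed the permutation test (exact permutation adjusted p = 0.0435), but not when stratified by number format (adjusted p = 0.0545). The median of the ligand and receptor list was 0.088, while its mean (-0.17) and its test pointed down (camera adjusted p = 0.531).

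The count of genes differing between B and A was 3861 among the 14 libraries that are not rounded (4 of A, 8 of B), 0 among the 8 rounded ones (2 of A, 2 of B; 1824 at an unadjusted p under 0.05), and 4914 with the number format as a covariate. With the squamous and the alveolar scores of each library as covariates, 1 gene was left, and the median standard error rose from 0.229 to 0.421. The alveolar score was at most -0.280 in A and at least -0.041 in B, so as a covariate it largely stands in for the group. With the squamous score alone as a covariate, 1729 genes differed.

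**Figure D2:**
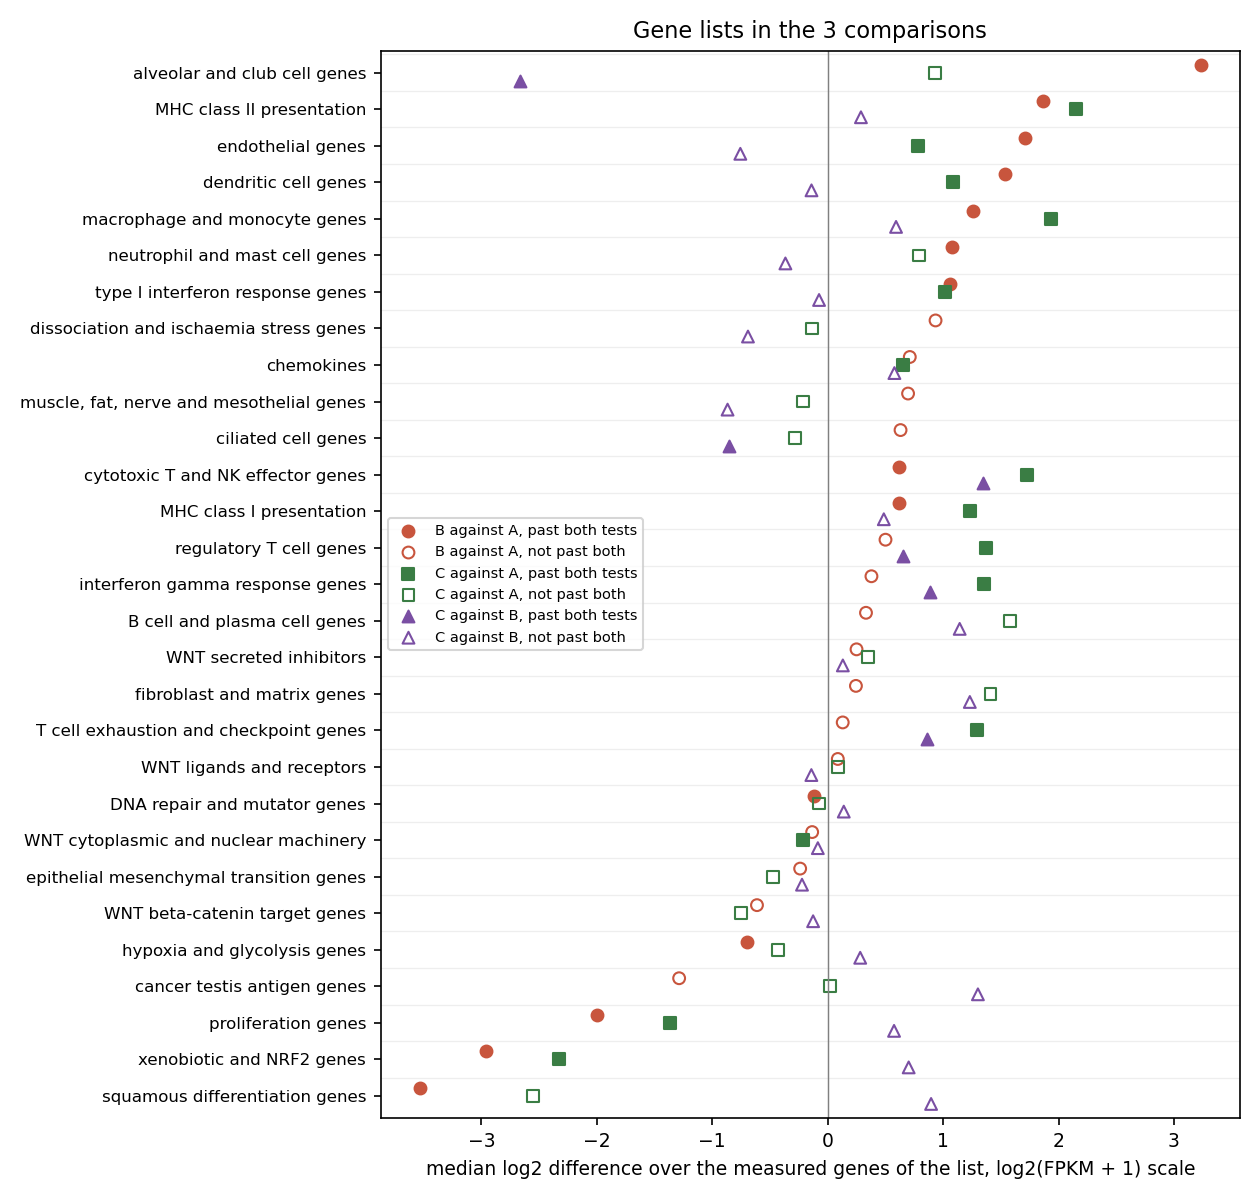
Median log2 difference of 29 gene lists in the 3 comparisons, on the log2(FPKM + 1) scale, with filled symbols for lists past both camera and the exact permutation test. Filled symbols number 14 for B against A, 14 for C against A and 6 for C against B, and the alveolar list ran from 3.23 in B against A to -2.67 in C against B.

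Tumours of group C had higher levels of T cell, antigen presentation and macrophage genes than tumours of group A, and lower levels of cell cycle genes. With an estimated correlation camera called 0 lists (7 at an unadjusted p under 0.05). In all, 3177 of 13442 genes differed, 1549 higher and 1628 lower in C, and 1024 and 760 of these differed by at least 1 on the log2 scale. Here too the majority turned with quantile normalisation (1627 higher, 1538 lower). ITGAL, the integrin subunit of LFA-1, stood at 23.6 ± 4.59 FPKM in C (SD, n = 6) against 3.76 ± 1.03 in A (SD, n = 6), a log2 difference of 2.38 (SE 0.20, limma adjusted p = 3.81e-07). The GTPase gene RAC2 (2.65), the signalling adaptor SASH3 (2.47), the actin regulator WAS (2.02) and the exchange factor VAV1 (2.02) were likewise higher in 6 of 6 libraries than the median of A. Lower in C were LSG1 (-1.55), the apoptosis regulator PAWR (-1.42), the epithelial transcription factor OVOL2 (-1.45) and CSNK2A3 (-1.33), an intronless copy of CSNK2A1 with which it can share reads.

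Lymphocyte lists were among those higher in C. Of 25 cytotoxic T and NK genes, 21 were higher, 0 lower and 4 did not pass (24 higher and 0 lower adjusted over the list alone), with a median log2 difference 1.72, 1.72 not rounded and 1.65 rounded (exact permutation adjusted p = 0.00897; adjusted p = 0.109 with an estimated correlation). CD3E stood at 60.3 ± 17.1 FPKM in C and 9.70 ± 3.58 in A, CD8A, the coreceptor of killer T cells, at 17.9 ± 12.8 and 3.50 ± 1.54 (log2 difference 1.94), and CST7 at 32.7 ± 19.3 and 4.46 ± 2.44. GZMB (0.98, limma adjusted p = 0.0851) and IFNG (0.93, adjusted p = 0.0555) did not pass. Of 18 exhaustion and checkpoint genes, 12 were higher, 1 lower and 5 did not pass (14 higher and 1 lower adjusted over the list alone), with a median log2 difference 1.29, 1.13 not rounded and 1.15 rounded (exact permutation adjusted p = 0.00897; adjusted p = 0.078 with an estimated correlation). The inhibitory receptor genes TIGIT (1.85), CD96 (1.87) and BTLA (1.34) were higher, while CD274 did not differ detectably (16.1 ± 12.8 FPKM in C, 17.7 ± 15.2 in A, adjusted p = 0.902). Of 12 regulatory T cell genes, 9 were higher, 0 lower and 3 did not pass (9 higher and 0 lower adjusted over the list alone), with a median log2 difference 1.37, 0.88 not rounded and 1.34 rounded (exact permutation adjusted p = 0.00897; adjusted p = 0.0654 with an estimated correlation). FOXP3 (1.49) and the costimulator ICOS (1.52) were both higher. B cell and plasma cell genes were higher in 12 of 21 cases (19 higher and 1 lower adjusted over the list alone, median log2 difference 1.58, 2.55 not rounded and 0.99 rounded). That list passed camera (camera adjusted p = 3.94e-07) but not the permutation test (exact permutation adjusted p = 0.0628; adjusted p = 0.297 with an estimated correlation), except when stratified by number format (adjusted p = 0.0430). IRF4 (1.70) and CD79B (1.98) were among its higher members.

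Antigen presentation, interferon and myeloid lists were also higher in C. MHC class II genes were higher in 12 of 16 cases (12 higher and 1 lower adjusted over the list alone, median log2 difference 2.15, 2.19 not rounded and 1.63 rounded, exact permutation adjusted p = 0.00897; adjusted p = 0.109 with an estimated correlation). The invariant chain gene CD74 stood at 2689 ± 1166 FPKM against 427 ± 265, and the activator CIITA had a log2 difference of 1.93. MHC class I genes were higher in 11 of 18 (14 adjusted over the list alone, median log2 difference 1.23, 1.34 not rounded and 0.52 rounded, exact permutation adjusted p = 0.00897; adjusted p = 0.229 with an estimated correlation). The immunoproteasome subunit PSMB10 (1.66) was among them. Interferon gamma response genes were higher in 13 of 20 (16 adjusted over the list alone, median log2 difference 1.35, 1.28 not rounded and 0.89 rounded, exact permutation adjusted p = 0.0157; adjusted p = 0.274 with an estimated correlation). Stratified by number format the permutation test did not call that list (adjusted p = 0.0552). The ubiquitin-like gene UBD (3.06) and APOL3 (1.77) were among its higher members. Type I interferon genes were higher in 4 of 22 (4 adjusted over the list alone, median log2 difference 1.02, 1.13 not rounded and 0.84 rounded, exact permutation adjusted p = 0.0338; adjusted p = 0.408 with an estimated correlation). Macrophage and monocyte genes were higher in 15 of 20 (15 adjusted over the list alone, median log2 difference 1.93, 1.79 not rounded and 1.25 rounded, exact permutation adjusted p = 0.0157; adjusted p = 0.19 with an estimated correlation). The complement gene C1QA stood at 348 ± 286 FPKM against 67.5 ± 63.99. Dendritic cell genes were higher in 7 of 13 (8 adjusted over the list alone, median log2 difference 1.09, 1.62 not rounded and 1.18 rounded, exact permutation adjusted p = 0.00897; adjusted p = 0.109 with an estimated correlation). CCR7, which guides these cells to lymph nodes, was higher by 1.90. Chemokines were higher in 8 of 24 (8 adjusted over the list alone, median log2 difference 0.65, 1.13 not rounded and 0.51 rounded, exact permutation adjusted p = 0.0157; adjusted p = 0.109 with an estimated correlation). CCL3 and CCL4, which have close copies, were higher by 1.92 and 1.53. Endothelial genes were higher in 4 of 18 (5 adjusted over the list alone, median log2 difference 0.78, 0.82 not rounded and 0.93 rounded, exact permutation adjusted p = 0.0157; adjusted p = 0.408 with an estimated correlation). Fibroblast and matrix genes were higher in 8 of 23 (11 adjusted over the list alone, median log2 difference 1.41, 1.54 not rounded and 1.22 rounded) and passed camera (camera adjusted p = 9.67e-06) but not the permutation test (exact permutation adjusted p = 0.0863; adjusted p = 0.367 with an estimated correlation). Neutrophil and mast cell genes, with 3 of 14 higher (3 adjusted over the list alone, median log2 difference 0.79, 1.48 not rounded and 0.39 rounded), did the same (camera adjusted p = 0.0149; exact permutation adjusted p = 0.111; adjusted p = 0.367 with an estimated correlation).

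Cell cycle genes were lower in C than in A. Of 26 proliferation genes, 0 were higher, 17 lower and 9 did not pass (0 higher and 24 lower adjusted over the list alone), with a median log2 difference -1.37, -1.15 not rounded and -1.30 rounded (exact permutation adjusted p = 0.0157; adjusted p = 0.367 with an estimated correlation). PCNA, the sliding clamp of DNA replication, stood at 48.8 ± 17.5 FPKM against 124 ± 29.99, and MKI67 did not pass (-1.25, limma adjusted p = 0.0588). Of 20 xenobiotic and NRF2 genes, 1 was higher, 15 lower and 4 did not pass (1 higher and 18 lower adjusted over the list alone), with a median log2 difference -2.33, -1.48 not rounded and -3.30 rounded (exact permutation adjusted p = 0.0493; adjusted p = 0.297 with an estimated correlation). Stratified by number format the permutation test did not call them (adjusted p = 0.0886). The glutathione peroxidase GPX2 stood at 24.5 ± 41.2 FPKM against 359.7 ± 413. Of 23 squamous genes, 0 were higher, 2 lower and 21 did not pass (0 higher and 1 lower adjusted over the list alone), with a median log2 difference -2.55, -1.13 not rounded and -2.70 rounded. Camera called that list (camera adjusted p = 5.96e-04), the permutation test did not (exact permutation adjusted p = 0.168; adjusted p = 0.563 with an estimated correlation), and SOX2 (-3.99) was one of the lower pair. Alveolar and club cell genes were not called, with 0 of 21 higher (median log2 difference 0.93), nor were ciliated cell (-0.28) or hypoxia and glycolysis genes (-0.43). DNA repair and mutator genes had 4 members higher and 7 lower of 24 and were not called (camera adjusted p = 0.948).

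WNT target genes were not called in C against A (camera adjusted p = 0.0878; exact permutation adjusted p = 0.347), with 1 of 24 higher, 4 lower and 19 not passing (1 higher and 4 lower adjusted over the list alone) and a median log2 difference -0.75, -0.37 not rounded and -0.77 rounded. The median was -0.23 without A replicate 6 and -0.43 without A replicate 5. KREMEN1 stood at 7.73 ± 5.27 FPKM in C against 37.5 ± 20.8 in A. The receptor-removing ligases RNF43 (-1.65) and ZNRF3 (-1.44) were lower as well, and TCF7, a transcription factor of the pathway that T cells also use, was higher (1.22). AXIN2 (-0.53, limma adjusted p = 0.595; 0.20 without A replicate 6, -0.32 without A replicate 5, -0.19 without C replicate 1 and -0.85 without A replicate 4), LEF1 (0.15, 0.836) and CTNNB1 (-0.39, 0.164) did not pass. Of 26 ligands and receptors, 2 were higher, 8 lower and 16 did not pass (3 higher and 8 lower adjusted over the list alone), with a median of 0.091 but a mean of -0.28 and a test pointing down (camera adjusted p = 0.459). The lower ones included WNT5A (-2.31), FZD6 (-1.61) and FZD3 (-1.01). The 28 genes of the cytoplasmic and nuclear machinery were called lower, with a median log2 difference -0.21, -0.19 not rounded and -0.34 rounded (exact permutation adjusted p = 0.00897; adjusted p = 0.298 with an estimated correlation), although 1 was higher, 6 lower and 21 did not pass (1 and 6 adjusted over the list alone). They included CSNK2A1 (-1.18), which can share reads with its copy, AMER1 (-1.06), DVL2 (-0.59) and TNKS (-0.92).

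The count for C against A was 2679 with the number format as a covariate and 1671 with the squamous and alveolar scores as covariates. It was 630 among libraries not rounded (4 of A, 2 of C; 541 of them higher) and 106 among rounded ones (2 of A, 4 of C), where fewer libraries also lower the count. With relative depth as a covariate, which also differs between these groups, it was 1322 (788 higher and 534 lower). Squamous genes were then no longer called by camera (median log2 difference -1.01 against -2.55 without the covariate, adjusted p = 0.0850). WNT target genes were called (-1.02 against -0.75, adjusted p = 0.0203).

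Between C and B, tumours of group C had higher levels of cytotoxic, checkpoint and regulatory T cell genes and lower levels of alveolar and club cell genes. With an estimated correlation camera kept the 3 T cell lists but not alveolar and club cell genes (adjusted p = 0.0742). In all, 708 of 13442 genes differed, 249 higher and 459 lower in C, and 127 and 329 of these differed by at least 1 on the log2 scale. With quantile normalisation the split was 423 higher and 379 lower of 802, so the balance between the directions depends on the scaling. SIRPG, a T cell receptor for CD47, stood at 10.2 ± 3.93 FPKM in C (SD, n = 6) against 2.49 ± 1.34 in B (SD, n = 10), a log2 difference of 1.72 (SE 0.26, limma adjusted p = 0.00108). The cytokine receptors IL21R (1.42) and IL2RB (1.53), the costimulator CD27 (1.83) and the lymphocyte receptors SLAMF1 (1.18) and SLAMF6 (1.30) were also higher. ELF3, an epithelial transcription factor, stood at 9.92 ± 9.19 FPKM in C against 73.4 ± 32.02 in B (log2 difference -3.03, SE 0.40, limma adjusted p = 4.02e-04). The receptor tyrosine kinases ERBB2 (-2.20) and ERBB3 (-2.94), the tight junction protein CGN (-2.51), the sodium pump subunit ATP1B1 (-2.30) and GPRC5A (-2.53) were lower too. Each of these genes lay beyond the median of B in 6 of 6 libraries of C.

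Of 25 cytotoxic genes, in C against B, 17 were higher, 0 lower and 8 did not pass (24 higher and 0 lower adjusted over the list alone), with a median log2 difference 1.35, 1.11 not rounded and 1.62 rounded (exact permutation adjusted p = 0.00362; adjusted p = 0.0417 with an estimated correlation). CD3E stood at 60.3 ± 17.1 FPKM against 21.5 ± 8.001, CD8A at 17.9 ± 12.8 against 5.07 ± 1.90, GZMB at 20.7 ± 8.54 against 7.78 ± 4.62 and IFNG at 3.48 ± 3.61 against 0.623 ± 0.365, with limma adjusted p of 0.00292, 0.0064, 0.0323 and 0.0291. EOMES, a transcription factor of killer cells, was higher by 1.23. Of 18 exhaustion and checkpoint genes, 7 were higher, 0 lower and 11 did not pass (12 higher and 0 lower adjusted over the list alone), with a median log2 difference 0.86, 0.79 not rounded and 1.23 rounded (exact permutation adjusted p = 0.00362; adjusted p = 0.012 with an estimated correlation). PDCD1, the gene of PD-1, stood at 3.56 ± 3.33 FPKM in C and 0.68 ± 0.36 in B, LAG3 at 9.67 ± 8.30 and 2.002 ± 1.48, and TNFRSF9 at 4.68 ± 3.31 and 0.856 ± 0.516. CD274 did not pass (1.13, adjusted p = 0.198). Of 12 regulatory T cell genes, 4 were higher, 0 lower and 8 did not pass (5 higher and 0 lower adjusted over the list alone), with a median log2 difference 0.65, 0.39 not rounded and 0.84 rounded (exact permutation adjusted p = 0.00362; adjusted p = 0.0239 with an estimated correlation). FOXP3 stood at 4.95 ± 1.65 against 2.06 ± 1.06 FPKM. Interferon gamma response genes were higher in 3 of 20 cases (12 adjusted over the list alone, median log2 difference 0.89, 0.61 not rounded and 0.76 rounded, exact permutation adjusted p = 0.0435; adjusted p = 0.206 with an estimated correlation). Stratified by number format that test did not call them (adjusted p = 0.168). UBD (2.11) and the inflammasome regulator GBP5 (1.62) were among them.

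Of 21 alveolar and club cell genes, in C against B, 0 were higher, 8 lower and 13 did not pass (0 higher and 18 lower adjusted over the list alone), with a median log2 difference -2.67, -1.33 not rounded and -3.11 rounded (exact permutation adjusted p = 0.00362; adjusted p = 0.0742 with an estimated correlation). MUC1 stood at 44.2 ± 35.1 FPKM in C against 330.0 ± 173 in B, AGER at 3.12 ± 2.56 against 37.98 ± 26.9, and CAV1 at 33.4 ± 5.57 against 107 ± 57.96. Of 9 ciliated cell genes, 0 were higher, 3 lower and 6 did not pass (0 higher and 4 lower adjusted over the list alone), with a median log2 difference -0.86, -0.61 not rounded and -0.66 rounded (exact permutation adjusted p = 0.0225; adjusted p = 0.225 with an estimated correlation), and stratified by number format the permutation test did not call them (adjusted p = 0.129). FOXJ1, the regulator of motile cilia, had a log2 difference of -1.46.

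The other 15 lists that camera called between C and B did not pass the permutation test. Stratified by number format it called 2 of them, B cell and plasma cell genes (adjusted p = 0.0286) and cancer testis antigens (0.0258). Fibroblast and matrix genes were higher in 6 of 23 cases (11 adjusted over the list alone, median log2 difference 1.23, 1.01 not rounded and 1.86 rounded, exact permutation adjusted p = 0.0688; adjusted p = 0.219 with an estimated correlation). COL1A1, a chain of fibrillar collagen, stood at 756 ± 643 FPKM against 126 ± 111, and COL11A1 was higher by 2.92. B cell and plasma cell genes were higher in 4 of 21 (12 adjusted over the list alone, median log2 difference 1.14, 1.82 not rounded and 0.68 rounded, exact permutation adjusted p = 0.0788; adjusted p = 0.206 with an estimated correlation). MZB1, of plasma cells, was higher by 1.88. DNA repair and mutator genes were higher in 3 of 24 (4 adjusted over the list alone, median log2 difference 0.14, 0.43 not rounded and -0.034 rounded, exact permutation adjusted p = 0.181; adjusted p = 0.279 with an estimated correlation). These were the cytidine deaminases APOBEC3C, APOBEC3D and APOBEC3G, close paralogs that lymphocytes also express. Endothelial genes were lower in 2 of 18 (9 adjusted over the list alone, median log2 difference -0.76, -0.99 not rounded and -0.43 rounded, exact permutation adjusted p = 0.0847; adjusted p = 0.361 with an estimated correlation). CA4, of lung capillaries, had a log2 difference of -2.27. Chemokines had 1 higher of 24 (1 adjusted over the list alone, median log2 difference 0.58, 0.57 not rounded and 0.087 rounded, exact permutation adjusted p = 0.12; adjusted p = 0.212 with an estimated correlation). The higher one was CCL11. Stress genes of dissociation and ischaemia had 1 lower of 20 (7 adjusted over the list alone, median log2 difference -0.69, -0.87 not rounded and -0.15 rounded, exact permutation adjusted p = 0.0847; adjusted p = 0.37 with an estimated correlation). The lower one was NR4A1, an immediate early gene. Muscle, fat, nerve and mesothelial genes had 1 lower of 8 (1 adjusted over the list alone, median log2 difference -0.87, -0.30 not rounded and -0.73 rounded, exact permutation adjusted p = 0.0833; adjusted p = 0.37 with an estimated correlation). The lower one was MSLN, a mesothelial gene.

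In 8 called lists no member passed. Proliferation genes had a median log2 difference 0.57, 1.11 not rounded and 0.14 rounded (adjusted p = 0.436 with an estimated correlation). MHC class I genes had a median log2 difference 0.49, 0.43 not rounded and 0.21 rounded (adjusted p = 0.293 with an estimated correlation). MHC class II genes had a median log2 difference 0.29, -0.021 not rounded and -0.091 rounded (adjusted p = 0.539 with an estimated correlation). Macrophage and monocyte genes had a median log2 difference 0.59, 0.38 not rounded and -0.00023 rounded (adjusted p = 0.354 with an estimated correlation). Squamous genes had a median log2 difference 0.90, 2.65 not rounded and 1.14 rounded (adjusted p = 0.596 with an estimated correlation). Cancer testis antigens had a median log2 difference 1.30, 2.42 not rounded and 0.80 rounded (adjusted p = 0.361 with an estimated correlation). Hypoxia and glycolysis genes had a median log2 difference 0.28, 0.66 not rounded and 0.40 rounded (adjusted p = 0.575 with an estimated correlation). Xenobiotic and NRF2 genes had a median log2 difference 0.70, 1.22 not rounded and 0.39 rounded (adjusted p = 0.436 with an estimated correlation). MKI67 (0.64, limma adjusted p = 0.421) and CD74 (0.57, adjusted p = 0.384) were among the members that did not pass.

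No WNT list was called between C and B, and no member of any of them passed. Target genes had a median log2 difference of -0.13 and a mean of -0.0078 over 24 genes, with a test that pointed up (camera adjusted p = 0.528; exact permutation adjusted p = 0.866). The median of the target genes was 0.03 without C replicate 1, -0.22 without C replicate 3, -0.21 without C replicate 5, -0.19 without B replicate 1 and -0.06 without B replicate 2. The medians were -0.14 for 26 ligands and receptors (camera adjusted p = 0.742), -0.085 for 28 machinery genes (camera adjusted p = 0.855) and 0.13 for 9 secreted inhibitors (camera adjusted p = 0.528). AXIN2 stood at 3.82 ± 2.31 FPKM in C and 4.77 ± 2.83 in B (log2 difference -0.29, SE 0.60, limma adjusted p = 0.831). LEF1 (0.88, adjusted p = 0.215), TCF7 (0.67, 0.265), CTNNB1 (-0.11, 0.768), WISP1 (1.30, 0.078) and WNT3 (-0.73, 0.0711) did not pass either. AXIN2 was 0.05 without C replicate 1, -0.48 without C replicate 2, -0.18 without B replicate 5 and -0.19 without B replicate 7. CTNNB1 was -0.04 without C replicate 6, -0.07 without C replicate 2, -0.05 without B replicate 6 and -0.18 without B replicate 5.

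The count for C against B was 435 with the number format as a covariate and 31 among libraries not rounded (8 of B, 2 of C, all 31 higher). Among rounded ones (2 of B, 4 of C) the count was 1, with 1270 at an unadjusted p under 0.05. With the squamous and alveolar scores as covariates the count was 8, and with the squamous score alone 864. It was 430 without C replicate 2 and 415 without C replicate 3.

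**Figure D3:**
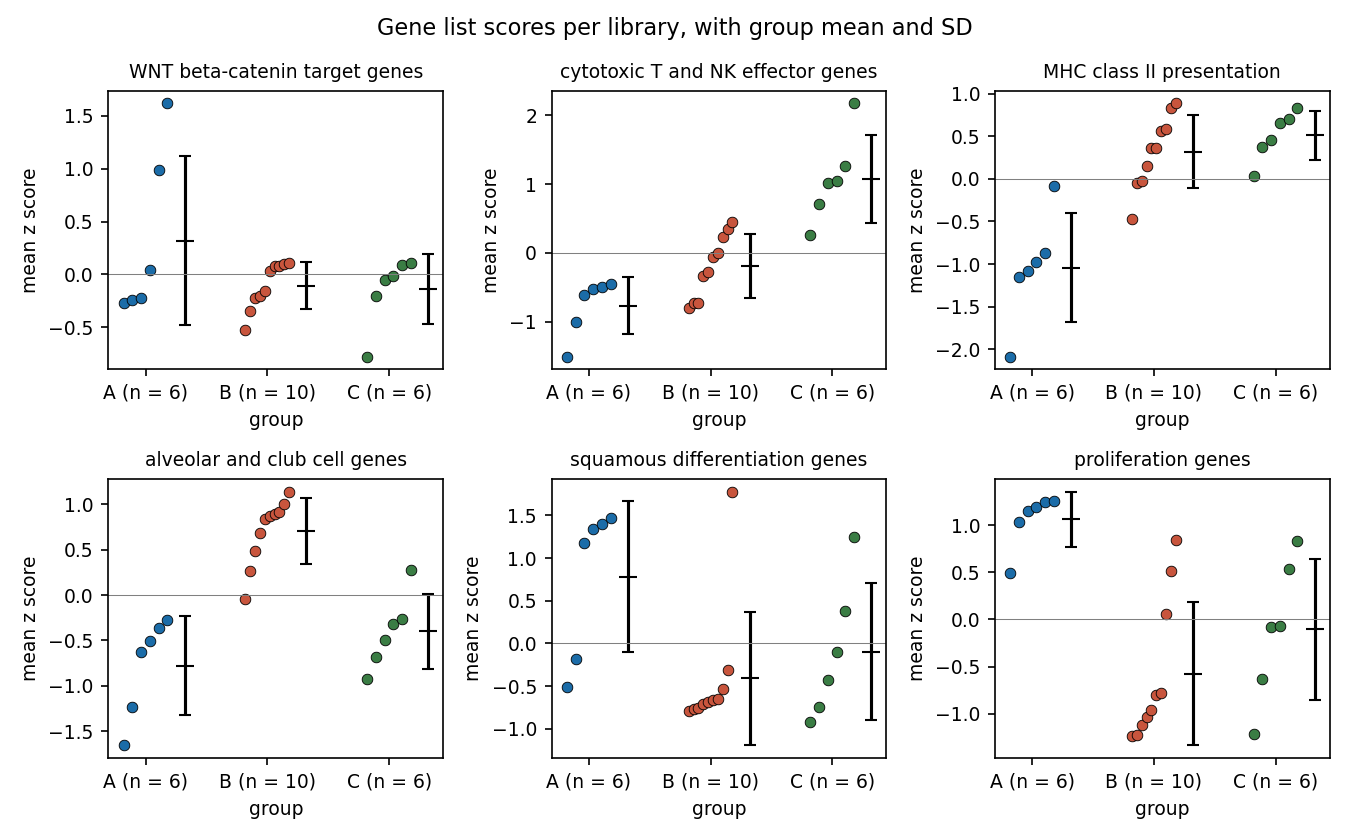
Scores of 6 gene lists, each the mean z score of its genes in log2(FPKM + 1), with 1 point per library sorted within its group and the group mean with SD beside the points. Cytotoxic scores averaged 1.08 ± 0.640 in C, -0.189 ± 0.464 in B and -0.766 ± 0.415 in A, while WNT target scores averaged -0.142 ± 0.331, -0.107 ± 0.219 and 0.320 ± 0.796.

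Because the series concerns WNT signalling and immune escape, the WNT target score of each library was set against 3 immune scores over the 22 libraries. The WNT target score includes TCF7, which T cells also use, so T cell content can enter both scores. No score without TCF7 was computed. Against the cytotoxic score, Pearson's r was -0.184 (permutation p = 0.408, adjusted over the 3 relations 0.485) and Spearman's rho 0.191 (permutation p = 0.391, adjusted 0.720). Without the 2 libraries farthest from the median WNT score, r was -0.0720. After centring on the group means it was 0.125, with the squamous and alveolar scores taken out -0.344 (permutation p = 0.119, adjusted 0.179), among the 14 libraries not rounded 0.0660 and among the 8 rounded ones -0.381. Against the interferon gamma score, r was -0.258 (permutation p = 0.245, adjusted 0.485) and rho -0.0469 (permutation p = 0.837, adjusted 0.837). There r was -0.143 without those 2 libraries, -0.441 with the squamous and alveolar scores taken out (permutation p = 0.0351, adjusted 0.105), -0.0833 among libraries not rounded and -0.333 among rounded ones. Against the dendritic cell score, r was -0.162 (permutation p = 0.485, adjusted 0.485) and rho 0.159 (permutation p = 0.480, adjusted 0.720). Here r was 0.342 without those 2 libraries, 0.351 after centring on the group means (permutation p = 0.0488, adjusted 0.146), -0.141 with the squamous and alveolar scores taken out, -0.166 among libraries not rounded and -0.161 among rounded ones. None of the 3 relations passed over the 22 libraries.

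Within single groups the sign of the relation to the cytotoxic score varied. In A, r was 0.615 (n = 6, permutation p = 0.137, adjusted 0.412) and rho 1.00 (permutation p = 0.00285, adjusted 0.00855), since both scores put the 6 libraries in the same order. In B, r was 0.555 (n = 10, permutation p = 0.0950, adjusted 0.285) and rho 0.394 (permutation p = 0.264). In C, r was -0.907 (n = 6, permutation p = 0.0187, adjusted 0.0562) and rho -0.771 (permutation p = 0.102). The same library of C had the lowest WNT target score (-0.778, next -0.203) and the highest cytotoxic score (2.18, next 1.27). The value of r in C without that library was not computed. Against the interferon gamma score, r was 0.111 in A, 0.0691 in B and -0.791 in C (in C permutation p = 0.0507, adjusted 0.0761). Against the dendritic cell score, r was 0.399 in A, 0.260 in B and 0.751 in C (in C permutation p = 0.132, adjusted 0.132). Whether these values differ between the groups was not tested.

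**Figure D4:**
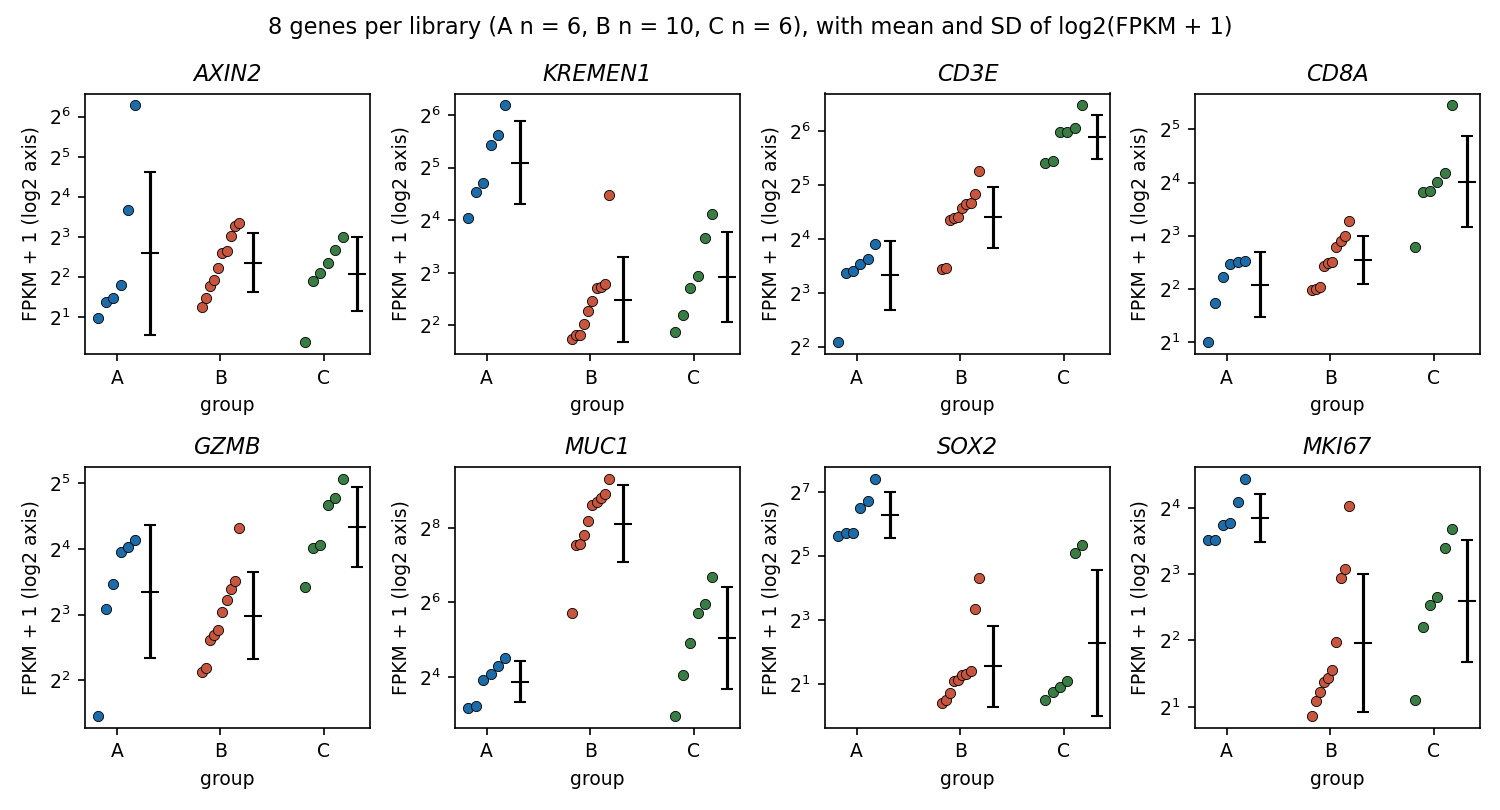
FPKM + 1 of 8 genes on a log2 axis, with 1 point per library sorted within its group and the mean with SD of log2(FPKM + 1) beside the points. For CD3E the 6 libraries of C (60.3 ± 17.1 FPKM) lay above the median of B, whereas AXIN2 overlapped between all 3 groups and its SD in A (15.9 ± 30.1 FPKM) came mostly from 1 library.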

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

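No test in this part was chosen after its result was seen. In each group, the gap between the highest or lowest library and the nearest of the others was divided by the range of the group, for every list and named gene, and compared with Dixon's 95% limit. Of 762 such tests, 49 passed (43 genes and 6 lists), where chance gives 38.1, so the number by itself is near that of chance. Each result below is a library far from the others of its group, with the share of the range.

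In group A the highest library stood apart for PECAM1 (0.642), APOL3 (0.672), PDCD1 (0.639), CLIC5 (0.702), MAGEA3 (0.703), MAGEA4 (0.859), UPK3B (0.703), TNFRSF18 (0.645) and WNT secreted inhibitors (0.698). The lowest library stood apart for CD3E (0.709), AQP1 (0.708), CD96 (0.629), SLAMF6 (0.845), UBE2C (0.645) and proliferation genes (0.701).

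In group B the highest library stood apart for LSG1 (0.595), KREMEN1 (0.614), HPGD (0.467), KDM3A (0.494), DSC3 (0.963), PERP (0.672), TP63 (0.633), AMER1 (0.518), BATF (0.476), ERBB2 (0.485), MAGEA6 (0.941), MAGEA3 (0.913), MAGEA4 (0.699), MAGEA11 (0.948), RSPH1 (0.469), COL11A1 (0.518), GPC1 (0.599), KRT5 (0.847), squamous differentiation genes (0.813) and cancer testis antigen genes (0.4931). The lowest library stood apart for MUC1 (0.507), APBB1IP (0.506), CSNK2A3 (0.484), CGN (0.471) and FOS (0.484). One library of B gave 11 of these results, among them the squamous list and the basal cell genes DSC3, KRT5 and TP63. No explanation of it was tested.

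In group C the highest library stood apart for CLEC14A (0.636), ICK (0.682), XCL2 (0.666), UBD (0.719), PDCD1 (0.765), FZD5 (0.638) and T cell exhaustion and checkpoint genes (0.649). The lowest library stood apart for B2M (0.644) and WNT beta-catenin target genes (0.650).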

How the results depend on the processing

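Over the alternatives run, 3321, 849 and 234 values of named genes, of lists, and of counts and relations were labelled the same. For named genes and called lists this means the same direction and side of the threshold. A list not called counted as the same if it stayed so, even where its median turned. A count was the same within a fixed factor of the reported one, whatever the balance of directions. Weaker were 549, 130 and 23, stronger 28, 38 and 1 and reversed 28, 18 and 5. Only a list called in the main test counts as reversed, if its median or the direction of its test turned. Turned medians of lists not called are therefore missing below, such as WNT ligands and receptors in B against A (0.088 pooled, -0.31 rounded). Reversed values and the counts and relations that changed follow as log2 differences (medians for lists), correlations or counts, and other weaker or stronger values are given here only as numbers. The cause was not tested, except that the alveolar and squamous lists are themselves covariates in 1 setting and smaller sets of libraries have less power. The settings by number format and depth and the leaving out of 3 libraries were chosen after seeing the data.

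With the stricter filter, C against B gave 449 genes. With array weights, C against B gave 1298 genes. C against A gave CD274 -0.060. With the squamous and alveolar scores as covariates, B against A gave 1 gene, SLC34A2 -0.16, SLC2A1 0.67, KIT -0.18, CD274 0.36, TCF7 -0.35, GZMB 0.71, IFNG 0.66, neutrophil and mast cell genes -0.22, alveolar and club cell genes 0.063, hypoxia and glycolysis genes 0.58. C against A gave 1671 genes, LEF1 -0.34, squamous differentiation genes 0.12. C against B gave 8 genes, IFI30 -0.14, GAPDH -0.54, P4HA1 -0.15, C1QC -0.30, C1QB -0.58, UPK3B 0.15, DES 0.33, PLK1 -0.19, MCM2 -0.26, MKI67 -0.33, AXIN2 0.94, 13 called lists, macrophage and monocyte genes -0.30, chemokines -0.10, alveolar and club cell genes 0.67, proliferation genes -0.30, hypoxia and glycolysis genes -0.38, muscle, fat, nerve and mesothelial genes 0.25. The F test gave 1188 genes. With the number format as a covariate, C against B gave 435 genes, MHC class II presentation -0.058. With relative depth as a covariate, C against A gave 1322 genes, LEF1 -0.089. Among the 14 libraries not rounded, C against A gave 630.0 genes. C against B gave 31 genes, CD74 -0.025, MHC class II presentation -0.021. The F test gave 2783 genes. B against A gave GZMB 0.072. Among the 8 rounded libraries, B against A gave 0 genes, cytotoxic T and NK effector genes 0.19. C against A gave 106 genes, FPR2 -0.032, LEF1 -0.11. C against B gave 1 gene, IFI30 -0.39, MKI67 -0.24, AXIN2 0.14, 12 called lists, MHC class II presentation -0.091, macrophage and monocyte genes -2.34e-04, DNA repair and mutator genes -0.034, dissociation and ischaemia stress genes -0.15. The F test gave 0 genes. Without 3 libraries that lie between A and B, B against A gave WNT beta-catenin target genes 0.15. With an estimated correlation in camera, B against A gave 0 called lists. C against A gave 0 called lists. C against B gave 3 called lists. With fry, C against B gave 7 called lists. With the exact permutation test, C against B gave 6 called lists. WNT target score against others, Spearman rho for cytotoxic T and NK effector genes 0.19, dendritic cell genes 0.16, Pearson r, centred on group means for cytotoxic T and NK effector genes 0.13, dendritic cell genes 0.35, Pearson r, without the 2 libraries farthest from the median WNT score for dendritic cell genes 0.34.

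With relative depth as a covariate camera also called WNT machinery genes (-0.095) and ciliated cell genes (0.68) for B against A and alveolar and club cell genes (0.92) for C against A, and it no longer called MHC class II genes (0.22) for C against B. Leaving out 1 library at a time gave 3846 to 5079 genes for B against A, 2219 to 3387 for C against A, 415 to 873 for C against B, 4098 to 5380 over the 3 groups, and 14 to 18 lists for B against A, 17 to 21 lists for C against A, 15 to 21 lists for C against B. The count for C against B fell to 415 without C replicate 3 and 430 without C replicate 2. In the 8 rounded libraries limma called 0 genes for B against A and 0 over the 3 groups, with 1824 and 2279 at an unadjusted p under 0.05. With an estimated correlation camera called 0 lists for B against A and 0 for C against A, with 3 and 7 at an unadjusted p under 0.05; fry called 15 and 17. No paired analysis was possible because each patient gave 1 library in 1 group. Absolute depth is unknown, so the counting error of genes with low values could not be set apart from other spread. Relative depth differs between C and A, so the lower count of genes there with depth as a covariate cannot be told apart from a loss of power. For squamous genes the median itself moved from -2.55 to -1.01, with no error computed for that move. Depth ran from 0.835 to 0.953 in C and from 0.944 to 1.40 in A, so the 2 groups hardly overlap in it. The moved median therefore does not show whether the lost call of squamous genes is one of power alone.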

Other observations

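The tests of explanations below were set out before their results were seen, except that the number format, relative depth, the leaving out of 3 libraries the checks of alveolar type 1 and ciliated levels, the groupings drawn within number format and the correlation within group A were chosen after seeing the data.

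Cell types of the lung epithelium differed in degree between B and A. The 10 alveolar type 2 genes, of the cells that make surfactant, had a mean log2 difference of 3.89 with 10 higher (exact permutation p = 2.50e-04). The 10 alveolar type 1 genes, of the flat gas exchange cells, had 1.28 with 6 higher (exact permutation p = 1.25e-04, the smallest this test can give). The 5 club and secretory genes had 3.15 with 3 higher (exact permutation p = 6.24e-04). Against B, group C had -2.63 for type 2 genes with 2 lower, -1.49 for type 1 genes with 7 lower and -2.58 for club genes with 2 lower. The 10 pan-leukocyte genes, carried by most white blood cells, had a mean log2 difference of 1.43 in B against A and 2.29 in C against A, with 10 of 10 higher in each, and 0.862 in C against B with 6 of 10 higher.

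Several lists were not called by camera in the comparisons given here. Epithelial mesenchymal transition genes (15 measured) had medians of -0.24 in B against A (4 higher, 4 lower), -0.47 in C against A (3 higher, 6 lower) and -0.22 in C against B (0 higher, 3 lower). Dissociation and ischaemia stress genes had 0.93 in B against A, with 7 of 20 higher and 1 lower, and -0.13 in C against A. Muscle, fat, nerve and mesothelial genes had 0.70 and -0.22, and WNT secreted inhibitors 0.25 (1 of 9 higher) and 0.35 (2 higher). Cancer testis antigens had a median of -1.29 in B against A (1 of 5 lower) and passed the exact permutation test there (adjusted p = 0.0273). In C against A their median was 0.023, while the mean was -0.26 and the test pointed down. Between C and B, type I interferon genes had a median of -0.075 and a mean of -0.10, dendritic cell genes -0.14 and -0.11, with a test pointing up for both, and neutrophil and mast cell genes a median of -0.37.

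The number format went with gene levels after the group means were taken out: 332 genes differed between the 14 libraries not rounded and the 8 rounded, 286 higher and 46 lower in those not rounded (2469 at an unadjusted p under 0.05). The genes with the smallest p-values were named after their values were seen, and no theme among them was tested. They included HIST3H2A (log2 difference -1.38), RP9 (1.07), NDUFAF7 (0.82), ACAD11 (0.96) and SIGLEC1 (-1.50). The splicing genes SRSF11 (1.01), PNN (1.10), CCNL1 (1.22), RBM25 (0.87) and HNRNPH1 (0.74) were also among them.

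Random groupings were set against the real one. The number of genes called was 4616 against at most 298 in the 99 others for B against A and 3177 against 2445 for C against A. It was 708 against 3 for C against B, and 4877 against 61 over the 3 groups. Only 1 grouping of 100, the real one, reached each count, so a random assignment of the libraries is argued against. If the groups were formed from these measurements, the real grouping would stand out by construction, and these draws cannot address that. The number of lists called was 15 for B against A, where 13 of 100 groupings called as many (at most 17), and 18 for C against A, where 10 did (at most 21), so chance cannot be excluded for these 2 counts of lists. For C against B it was 21 against at most 20 in the others (1 of 100). Leaving out 1 library at a time gave 15 to 21 lists there, so that margin is too narrow to exclude chance. The random groupings ignored the number format. Drawn within it, the others called at most 231, 900 and 413 genes for B against A, C against A and C against B, so 1 of 100 again reached each count. As many lists were called by 17, 12 and 1 of 100.

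Cytotoxic genes were higher in C than in B. The number format is argued against as the whole cause, since the median log2 difference among the 14 libraries not rounded was 1.11 and the permutation test stratified by format gave an exact p = 0.00148. More leukocytes of every kind in C stay open. Cytotoxic genes rose by 0.331 more than pan-leukocyte genes, with an exact permutation p = 0.229, which does not separate the 2. Most white blood cells carry pan-leukocyte genes, T cells among them, so added T cells alone could raise both lists. The contrast therefore cannot tell added T cells from more leukocytes of every kind. The leukocyte lists did not all rise. Mean log2 differences were 0.98 for B cell and plasma cell genes and 0.60 for macrophage and monocyte genes. They were -0.11 for dendritic cell genes and -0.28 for neutrophil and mast cell genes. Whether these differ from the pan-leukocyte rise was not tested. A difference in biology between the groups was not tested and stays open.

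Alveolar and club cell genes were higher in B than in A. The number format is argued against by a median of 3.21 among libraries not rounded (stratified exact p = 3.37e-04), and squamous differentiation in some libraries of A by 2.92 with the squamous score as a covariate, where 15 of 21 members passed. More normal lung tissue in B remains possible, although the result set out for its exclusion was met. Type 2 genes rose by 2.61 more than type 1 genes (exact permutation p = 0.00125) and 3.20 more than ciliated genes (exact permutation p = 9.99e-04). That bound asked for equal rises, and the design holds no normal lung to show how far each would rise. Of 10 type 1 genes 5 already stood at 10 FPKM or more in A, and 1 of these was higher in B against 5 of the other 5. That split, chosen after seeing the data, favours rises among genes low in A. It cannot account for ciliated genes, of which 8 of 9 stood below 10 FPKM in A. Ciliated genes rose from a median of 1.09 to 3.89 FPKM (3 of 9 higher) and type 2 genes from 18.4 to 586. Adenocarcinoma histology, which the labels do not give, was not tested.

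WNT target genes were lower in B than in A by camera, but not with an estimated correlation (adjusted p = 0.519). Nor were they called by fry (fry adjusted p = 0.0864) or in the permutation test (exact adjusted p = 0.155). One library of A as the cause cannot be told apart from the group. The highest median after leaving out 1 library of A was -0.302, next to the bound of -0.3. It lay within 0.2001 of that bound, the SD of the medians after each such omission. Those medians share libraries, so the SD is not a sampling error of the median. Squamous differentiation in some libraries of A is argued against only by a correlation chosen after seeing the data. The WNT target and squamous scores ran opposite within A (r = -0.929, n = 6, exact permutation p = 0.0417). With the squamous and alveolar scores as covariates the median was -0.742 (camera adjusted p = 0.00630, and 1.31e-04 to 0.808 over the alternatives). That lies within 0.497, the SE of the list's mean difference in this fit, of the bound of -0.3. The covariates therefore do not decide it. Without 3 libraries that lie between A and B the median was 0.15. The 2 libraries of A left out there are the 2 with the high WNT target scores (0.990 and 1.62). The other libraries of A scored -0.267 to 0.038, within the range of B (-0.525 to 0.109). The lower median of the list in B therefore rested on those 2 libraries and was not shared by the rest of A. A difference in WNT signalling between the groups was not tested apart from these.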
